A study of Mus musculus with 20 samples.

How the data were processed

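Brain cells of p16-3MR mice were captured with droplet-based 3′ single-cell chemistry and sequenced as 20 libraries, per the labels 1 mouse each, in 4 age groups: young (4 to 6 months, n = 4), middle-aged (10 to 17 months, n = 4), aged (18 to 20 months, n = 4) and very aged (21 to 32 months, n = 8). The deposited files hold UMI counts per cell and gene, made by the authors with Cell Ranger, and per the file headers its versions differ between libraries. The values carry no normalization, and cells had been called by Cell Ranger with settings that are not stated. The notes of the submitters name Cell Ranger 9.0.1 and the mouse build GRCm39, while 14 libraries list 32285 genes and 6 list 33696, and the kit and the number of animals in the design text differ from those in the labels. The label of each library was used for its group. No feature of the 3MR transgene is listed, so that the transgene could not be counted, and no genome positions are given because the annotation at hand belongs to another build. Genes were matched by Ensembl identifier, and the 31950 that both lists hold were kept, with 29 symbols that stand for more than 1 identifier kept apart.

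Cells with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept, 185493 in all. Doublets were scored per library with Scrublet as written in scanpy 1.11.5. Its automatic threshold called under 0.5% of cells in 3 libraries, so that the highest scores were removed instead up to an expected share of 0.8% per 1000 cells, which removed 15360 cells (8.28%, and 2.99% to 13.3% by library) and left 170133. Equal numbers of cells per library (up to 2500) were clustered on 2500 variable genes and 40 principal components with 20 neighbours and the Leiden method at resolution 1.2 (leidenalg 0.10.2), and the other cells joined the cluster of most of their 15 nearest neighbours. The 37 clusters were named from marker lists. The rule for naming them was settled after the cluster profiles were seen, and 4 clusters (5777 cells, 3.40%) that were led by markers of more than 1 class, or of none, stayed unnamed. Among the 10 leading genes against all other cells, 4 named clusters (3 of microglia, 1 of pericytes) held more markers of another class than of their own, and these were also left out as an alternative. They are called clusters led by another class below, though in some the lead was 1 marker against 0. Endothelial cells (up to 500 per library) were clustered again and named as arterial, capillary, venous or fenestrated, with clusters led by none of these left unnamed, again by a rule settled after the profiles were seen. Clusters led by immediate early or heat shock genes were kept among the capillary cells.

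The library was the replicate in every test. The share of each of 12 classes among a library's kept cells was compared on the log2 scale with a pseudocount of 0.5 cells, by exact two-sided permutation of the group labels (495 regroupings for 4 against 8 libraries, 70 for 4 against 4, where the smallest p is 0.0286), and over the order of the age groups by Spearman's correlation with 100000 permutations, with Benjamini-Hochberg adjustment over the classes of a comparison. Shares of endothelial types were compared in the same way on the percent scale in libraries with at least 50 endothelial cells. The share of cells with a Cdkn2a or Cdkn1a UMI was taken after each cell was thinned at random to 1000 UMIs, with shallower cells left out, and compared with the same share in other classes.

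For gene tests, UMIs were summed over the cells of a class in each library with at least 20 such cells. The sums were tested with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F test) over all age groups with the gene annotation of the library as a second term, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Very aged, aged and middle-aged libraries were each compared with the young ones, and the order of the groups was tested as a trend. The difference between the very aged effect in endothelial cells and that in microglia, astrocytes or oligodendrocytes was tested as an interaction with the library as a block. A set of 27 gene lists was tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry (limma 3.58.1). DESeq2 1.42.0 served as a second tool. Numbers were computed in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, matplotlib 3.10.9) and R 4.3.3.

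The comparisons, the gene lists, the marker lists and the rule for the genes to be named were fixed before the data were examined. In endothelial cells of very aged against young brains the rule named Cdkn2a and Cdkn1a, up to 12 risen and 12 fallen genes with the smallest adjusted p (log2 fold change of at least 0.5, average log2 CPM of at least 4, and no other class at 10 times the endothelial level or more), and up to 4 members of each list. Other comparisons took 3 or 5 genes per direction, with at least 0.2 per step for the trend. A few genes that the rule selects are not given in the text, though the counts over named genes include them. List members were named only where they passed, and Cdkn1a and Cdkn2a were added to the other endothelial, microglial and class comparisons after their values were seen.

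Library depth was 10821894 to 60731988 UMIs. The precision this gives was tested on simulated data, with 100 genes changed by 1 and by 0.5 on the log2 scale. In very aged against young endothelial cells 85% and 46% were called, and 2.96% of calls were of unchanged genes. The trend gave 86%, 45% and 4.38%, microglia 82%, 50% and 6.38%, astrocytes 59%, 9% and 2.86%, and the interaction with microglia 63%, 18% and 1.22%. Libraries were checked for duplicates over 92 pairs, of which the lowest chi-square per gene was 2.09, and none was a copy. Replicate numbers did not pair libraries: over the 24 pairs with the same number the median correlation was 0.016, and over the others 0.017. They were still used as a block in an alternative.

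Alternatives changed 1 choice at a time: the normalization, the low-count filter, the tool, the annotation term, the batch date, the cell filter, the handling of doublets, the resolution of clusters, the thinning depth, the libraries of 1 date or annotation, and each library left out in turn. Alternatives chosen after the data were seen left out the middle-aged or aged libraries, young 2 with very aged 6, clusters led by genes of another class, or used the automatic doublet threshold. Group labels were also shuffled, over all regroupings where there were at most 100 and 100 drawn at random otherwise (40 for the class interactions). Raw reads were not used.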

Results

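Single-cell RNA sequencing profiled brain cells of p16-3MR mice, a transgenic line in which a reporter and a drug-inducible killing gene follow the promoter of p16, the cell cycle inhibitor encoded by Cdkn2a. The labels place 20 libraries, 1 per mouse, in 4 age groups: young (4 to 6 months, n = 4), middle-aged (10 to 17 months, n = 4), aged (18 to 20 months, n = 4) and very aged (21 to 32 months, n = 8). The series asks how cells of the brain microcirculation, endothelial cells first among them, age and become senescent. The young libraries held 36624167 to 54496379 UMIs, the middle-aged 10821894 to 60731988, the aged 26891336 to 50235043 and the very aged 13861486 to 42522032. After filters and removal of doublets, 170133 cells were analysed. In data simulated at the depth of the endothelial libraries, 85% of genes changed by 1 on the log2 scale were called between very aged and young, and 46% of those changed by 0.5.

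Some libraries stood apart in ways the labels do not describe. The 4 middle-aged libraries, labelled male, held Xist, the RNA that silences an X chromosome in female cells, at 828 to 1130 CPM (counts scaled to the library total), and at most 0.0922 CPM of the Y-linked transcripts Eif2s3y, Uty and Kdm5d together, with Ddx3y at 1.66 to 4.05. The other 16 libraries held 0.0585 to 4.29 CPM of Xist and at least 190 of those 3 transcripts together, with Ddx3y at 90.9 to 128. In the 4 aged libraries, immediate early and heat shock genes, which respond to tissue handling, took 0.0821% to 0.112% of microglial UMIs, against 0.599% to 1.81% in the other 16. The first 4 very aged libraries share a batch date with all younger ones, and the last 4 have a later date. The libraries also follow a pair of gene annotations: 6 of them (young 3 and 4, very aged 5 to 8) list a larger set of genes and the other 14 a smaller set.

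The shares of cell classes address whether ageing changes which cells the brain yields. T or NK cells, the lymphocytes that are scarce in young brain, made up 2.20% ± 1.13 (SD, n = 8) of cells in very aged brains and 0.311% ± 0.124 (SD, n = 4) in young ones. Middle-aged brains held 0.812% ± 0.237 (SD, n = 4) and aged brains 0.151% ± 0.0926 (SD, n = 4). Endothelial cells made up 20.8% ± 8.24 of cells in very aged and 19.5% ± 7.53 in young brains, and microglia, the resident immune cells, 52.4% ± 10.8 and 49.8% ± 10.3. Of 12 classes, T or NK cells alone passed between very aged and young, with a log2 difference of 2.76, a larger share in 8 of 8 very aged libraries than in every young library, and adjusted p = 0.0242 (exact two-sided permutation test, p = 0.00202). The share also rose over the order of age groups (Spearman's rho 0.68, permutation p = 0.00149, adjusted p = 0.0179, n = 20), but this call ended within the first batch date (rho 0.437, adjusted p = 0.482) and within the larger annotation (0.828, adjusted p = 0.320). With fewer libraries the smallest p that the test can give no longer passes alone for 1 class of 12, and the call between very aged and young ended while the difference stayed. The log2 difference was 2.54 within the first batch date (exact p = 0.0286, adjusted p = 0.294), 2.93 within the larger annotation (exact p = 0.0667, adjusted p = 0.320), 2.96, 2.52, 2.68 and 2.87 without young 1, 2, 3 and 4 (exact p = 0.00606, adjusted p = 0.0727 each), and 2.54 with replicate numbers as a block (exact p = 0.125). Each of these p is the smallest that its libraries can give.

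**Figure D1:**
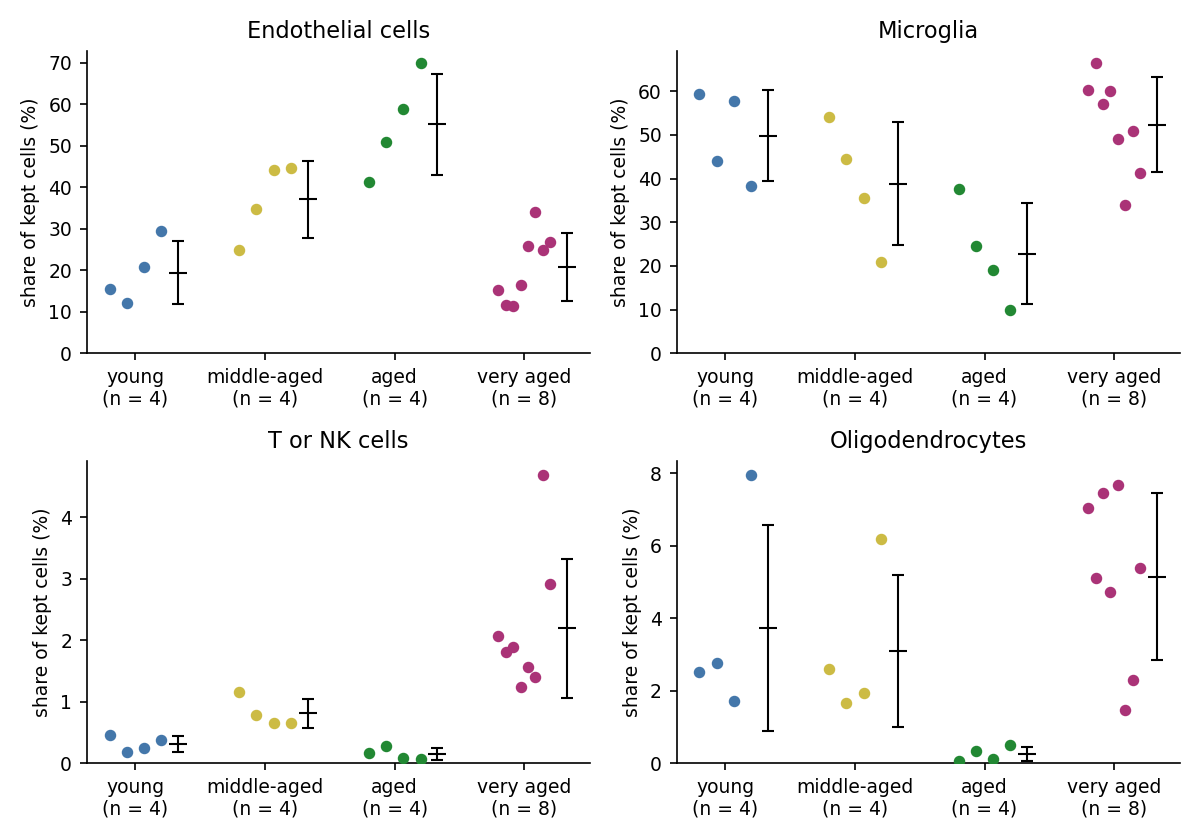
Share of kept cells in 4 cell classes by age group, in percent of each library's kept cells. Points are libraries and bars show the mean and SD, with T or NK cells at 1.23% to 4.69% in the very aged libraries and 0.175% to 0.452% in the young ones.

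The aged brains yielded a different mixture from the young ones. Endothelial cells made up 55.2% ± 12.2 of their cells (SD, n = 4; log2 difference 1.56) and microglia 22.8% ± 11.6 (−1.26). Astrocytes fell to 0.188% ± 0.165 (−4.74), oligodendrocytes, the myelin-forming cells, to 0.252% ± 0.1997 (−4.00), choroid plexus epithelium to 0.0443% ± 0.0808 (−5.65), neuroblasts or neural progenitors to 0.0219% ± 0.0154 (−4.66) and smooth muscle cells to 2.16% ± 0.364 (−1.04). All 4 aged libraries lay beyond all 4 young ones for each of these 7 classes, which gives the smallest p that 4 against 4 can reach (exact permutation p = 0.0286, adjusted p = 0.0490). These are the libraries with the low share of immediate early and heat shock genes. No class passed under the stricter cell filter, at Leiden resolution 0.6, with replicate numbers as a block (where 4 pairs give no p under 0.125), among cells outside the most abundant class, or without any 1 library other than aged 1, and smooth muscle cells turned direction under the stricter filter (log2 difference 0.91). In middle-aged brains no class passed the exact permutation test after adjustment, and T or NK cells (log2 difference 1.42, higher in 4 of 4 libraries) and neuroblasts or neural progenitors (−1.46, lower in 4 of 4) came closest (p = 0.0286, adjusted p = 0.171 each).

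Endothelial cells were separated into arterial, capillary, venous and fenestrated types, since the series also asks about loss of microvessels. Capillary cells made up 52.9% ± 4.36 of endothelial cells in very aged brains (SD, n = 8) and 46.9% ± 8.98 in young ones (SD, n = 4). Arterial cells made up 15.02% ± 4.24 and 20.0% ± 4.06, and venous cells 17.9% ± 5.65 and 19.9% ± 4.01. None of the 3 differences passed an exact permutation test (capillary 5.99 percentage points, p = 0.154, adjusted p = 0.230; arterial −4.97, p = 0.0869, adjusted p = 0.230; venous −1.97, p = 0.541). All 3 turned direction at Leiden resolution 0.6, to −5.90, 1.99 and 2.73 points. A share of endothelial cells is not a density of vessels.

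Cdkn2a, which encodes p16, and Cdkn1a, which encodes p21, are the inhibitors by which senescent cells are commonly recognised. A Cdkn2a UMI was found in 7 of 12316 endothelial cells of very aged brains and in 3 of 6162 of young brains, after each cell was thinned to 1000 UMIs. These are 0.0572% ± 0.0649 (SD, n = 8) and 0.0613% ± 0.0944 (SD, n = 4) by library, and the exact permutation test gave p = 0.937. The share in microglia was higher, 0.218% ± 0.0902 in very aged and 0.150% ± 0.0589 in young brains. Oligodendrocytes, which served as background, gave 2 of 3020 cells in very aged and 0 of 1145 in young brains. Median depth before thinning was 1760 UMIs in very aged and 3288 in young endothelial cells, and 2719 and 4233 in microglia. Aged brains gave 9 of 15506 and middle-aged brains 5 of 10278 endothelial cells (exact p = 1 and p = 0.914). A difference in Cdkn2a was not detectable at this depth, and its summed counts were too low for the gene test in endothelial cells.

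Cdkn1a was common in endothelial cells at every age. After thinning, 13.2% ± 3.55 of endothelial cells had a UMI in very aged brains (SD, n = 8), 11.3% ± 2.87 in young, 19.1% ± 7.05 in middle-aged and 9.84% ± 1.61 in aged brains (SD, n = 4 each). In oligodendrocytes the shares were 0.556% ± 0.423 in very aged and 0.103% ± 0.206 in young brains, at median depths of 3535 and 7493 UMIs. None of the endothelial differences from young passed an exact permutation test (p = 0.380 for very aged, 0.429 for aged, 0.0857 for middle-aged). Without thinning, the difference between very aged and young turned from 1.93 to −8.77 percentage points. In summed counts the log2 fold change of Cdkn1a was 0.24 (SE 0.27, adjusted p = 0.651) for very aged, −0.03 (SE 0.32, adjusted p = 0.964) for aged and 1.09 (SE 0.33, adjusted p = 0.0643) for middle-aged against young. The middle-aged change was called by DESeq2 (1.07, adjusted p = 0.0109), and in the main test when young 1 or middle-aged 1 was left out.

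**Figure D2:**
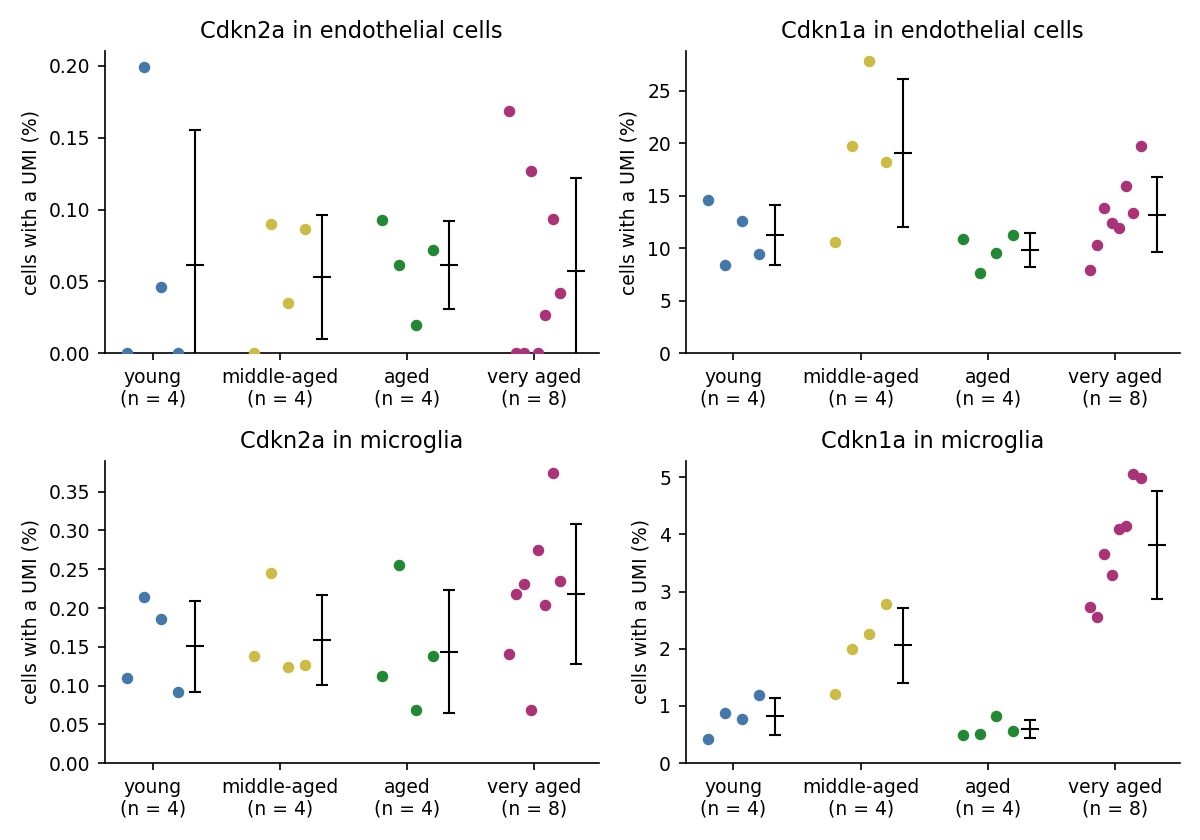
Share of cells with a Cdkn2a or Cdkn1a UMI after thinning to 1000 UMIs, in endothelial cells and microglia, in percent of cells by age group. Points are libraries and bars show the mean and SD, with Cdkn1a in microglia at 2.55% to 5.06% of cells in the very aged libraries and 0.421% to 1.19% in the young ones.

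Genes of very aged endothelial cells were compared with young ones to find what changes in the vessel wall. Among genes with an average log2 CPM of at least 4 the rise with the smallest adjusted p was in Npas2, a circadian transcription factor (log2 fold change 1.40, SE 0.12), from 27.8 ± 3.99 CPM (SD, n = 4) to 72.5 ± 8.91 (SD, n = 8), with up to 4.80 times the endothelial level in another class. Hdac9, a histone deacetylase (0.80, SE 0.08), Naip2, an inflammasome sensor (1.27, SE 0.13), Rasgrf2 (0.86), Thrb, a thyroid hormone receptor (0.70), Cp, the copper oxidase ceruloplasmin (0.74), P2ry1, a receptor for ADP (0.93), Stmn2 (0.76), Eml5 (0.72) and Fmo1 (0.50) rose with it. The fall with the smallest adjusted p was in Marveld2, which encodes tricellulin of tight junctions (−1.33, SE 0.11), from 34.6 ± 3.65 to 13.8 ± 2.18 CPM. Nrep (−1.02, SE 0.13), Pomc, the precursor of melanocortins (−1.31), Pde4d, a cAMP phosphodiesterase (−0.88), Pcdh19, a protocadherin (−0.93), Ubb, which encodes ubiquitin (−0.74), Pink1, a kinase of mitochondrial quality control (−0.59), Tprgl (−0.58), Cenpb (−0.57), Hnrnpa3 (−0.54), Shld1 (−0.54) and Ramac (−0.71) fell. Each of these lay beyond all 4 young libraries in 8 of 8 very aged libraries, except Ramac in 7. Grik1 (6.22) and Pcdh11x (1.96) also rose. Grik1 stood at 64.0 to 140 CPM in very aged 5 to 8, the later batch date, and at 1.44 or less in all 16 others, and Pcdh11x was highest in the middle-aged libraries with Xist (129 CPM).

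In all, 1369 of 13692 genes passed in very aged endothelial cells (edgeR, adjusted p under 0.05), 841 higher and 528 lower. Within the smaller annotation 890 passed and within the larger 762, within the first batch date 1034, and with replicate numbers as a block 853. Without young 4 the count was 774, and without young 2 and very aged 6, doubted for their cell yields, 825. Tested apart in the annotations, which share no library, 73 genes passed as higher in both against 13.4 expected by chance. As lower 27 passed against 8.08, with 8 in opposite directions. In the larger one age and batch date cannot be told apart, since its very aged libraries alone have the later date. Log2 fold changes of the annotations correlated at 0.344. Of 1312 main calls tested in both, 99.7% had the same direction and 100 passed in both. The main calls were made on these same libraries, so that their shared direction is largely built in and is no independent replication.

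**Figure D3:**
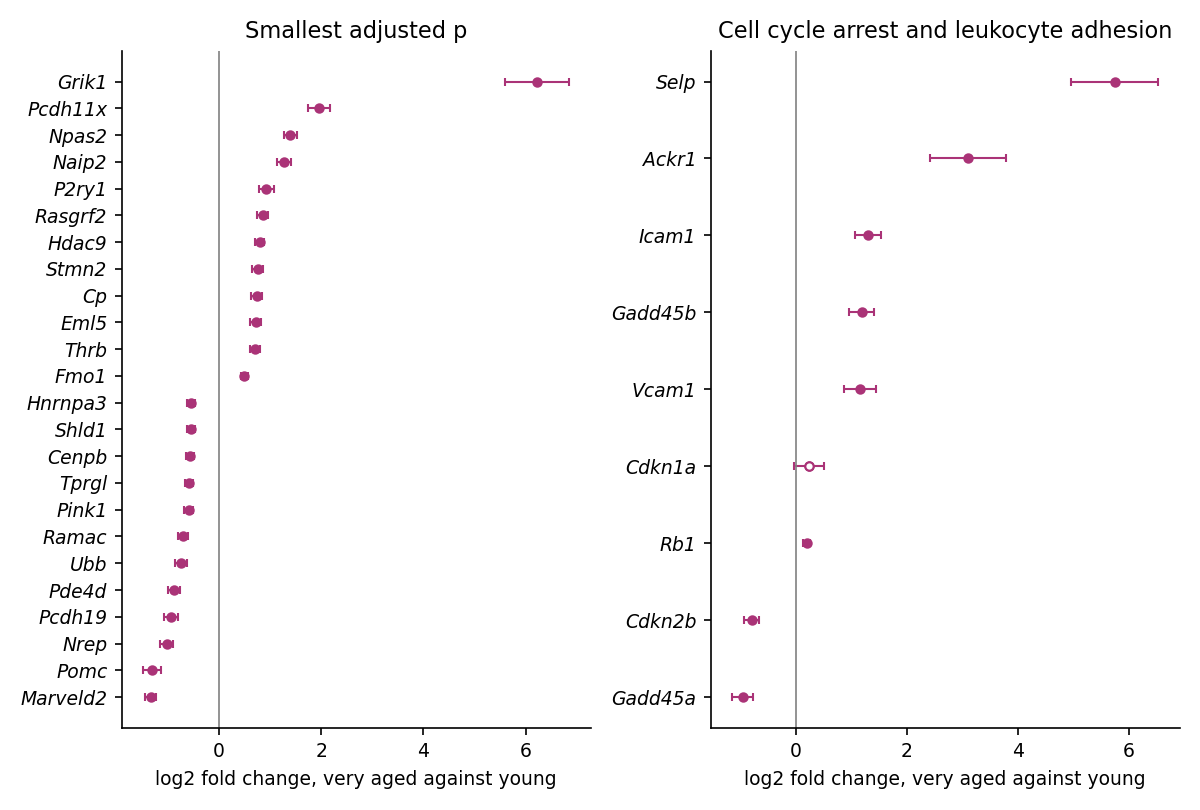
Log2 fold change of very aged (n = 8) against young (n = 4) endothelial cells, with bars of 1 SE, for the genes with the smallest adjusted p and for genes of the cell cycle arrest and leukocyte adhesion lists. Filled points passed the test and the open point, Cdkn1a at 0.24, did not.

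Some genes by which vessels bind leukocytes rose in very aged endothelial cells. Of 11 measured members of the leukocyte adhesion list, 5 rose, none fell and 6 did not pass (8 higher and 1 lower adjusted over the list alone). Selp, or P-selectin, went from 0.0973 to 6.62 CPM (log2 fold change 5.74, SE 0.79), Ackr1, a chemokine receptor of venules, from 7.37 to 71.8 (3.09, SE 0.68), Icam1 from 40.8 to 102 (1.30, SE 0.24) and Vcam1 from 118 to 286 (1.16, SE 0.28). These 4 were higher in 8 of 8 very aged libraries than in every young one. The other risen member was Lcn2, an iron-scavenging acute phase protein (3.69). It was among the 10 leading genes of venous endothelial clusters and of a neutrophil cluster, and RNA from neutrophils was not tested as its source. The list as a set was higher (camera adjusted p = 4.74e-07), with adjusted p = 0.104 with an estimated correlation. Of 61 members of the senescence secretory list, 16 rose and 2 fell (23 and 2 adjusted over the list alone). Examples were the growth factor Csf1 (1.04, SE 0.16) and Ptbp1 (0.64, SE 0.11), a splicing factor, each higher in 8 of 8 very aged libraries, where the level expected from microglial RNA was 0.0875 and 0.0427 of that observed. The chemokine Ccl5 rose in 8 of 8 too (3.44, SE 0.57), to 3.39 CPM, but it was the first leading gene of the T or NK cluster, and RNA from those cells, whose share rose, was not tested as its source. The cytokine Tnf was also higher in 8 of 8 (2.12, SE 0.31), but the level expected from microglial RNA was 1.36 times that observed, and a log2 difference of −0.12 was left after its subtraction. This list alone passed as a set both ways (camera adjusted p = 1.4e-06, and adjusted p = 0.0370 with an estimated correlation).

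The disease-associated microglia list, a marker list of another cell type, moved with them. Of its 23 measured members 7 rose and 1 fell in endothelial cells (15 and 1 adjusted over the list alone), among them the chemokines Ccl3 (1.61) and Ccl4 (1.89), and Cst7 (3.35). Its camera adjusted p was 1.23e-07, and adjusted p = 0.175 with an estimated correlation. None of the 15 homeostatic microglia genes passed (camera adjusted p = 0.957, median log2 fold change −0.08), its median was above 0 within the first batch date (0.34) and the smaller annotation (0.38), and fry gave the direction as up. Microglial RNA made up an estimated 5.06% ± 2.54 of UMIs in very aged endothelial cells (SD, n = 8) and 3.95% ± 2.07 in young ones (SD, n = 4). Immediate early and heat shock genes were split, with 1 of 24 higher and 2 lower (4 and 2 adjusted over the list alone), camera adjusted p = 0.255 and a median of 0.20 that turned with replicate numbers as a block (−0.21).

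Antigen presentation and interferon genes rose in part. The interferon response list had 3 of 33 members higher and none lower (4 higher adjusted over the list alone), namely Isg15 (1.30, higher in 7 of 8 very aged libraries than in every young one), Usp18 (0.52) and Ifi27l2a (0.85). MHC class I had 3 of 15 higher, H2-Q6 (1.18), H2-Q7 (1.67) and their activator Nlrc5 (0.93), and 5 adjusted over the list alone. MHC class II had 2 of 6 higher, Cd74 (1.55) and H2-Ab1 (1.15), the same number adjusted over the list alone. The reactive astrocyte list had 4 of 10 higher, which include Lcn2, an iron-scavenging acute phase protein (3.69, SE 1.01), the complement gene C4b (1.54) and the cytokine receptor Osmr (0.52), 4 adjusted over the list alone. The oligodendrocyte ageing and stress list had 1 of 7 higher, C4b, and 2 adjusted over the list alone. These lists passed camera (adjusted p = 0.00279, 0.00284, 0.00587, 0.00168 and 0.00997), but gave adjusted p = 0.650, 0.492, 0.238, 0.175 and 0.104 with an estimated correlation. Except for the interferon list, they also missed the threshold within the first batch date and within the smaller annotation.

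Some genes of protein synthesis and respiration fell, though most of each list did not pass. Of 76 ribosomal protein genes 22 fell and none rose (35 lower adjusted over the list alone), with a median log2 fold change of −0.29. Rpl10 fell the furthest of those named, from 377 to 184 CPM (−1.05, SE 0.23), and Rps24 (−0.44), Rpl28 (−0.42) and Rpl21 (−0.38) followed. Of 53 nuclear genes of oxidative phosphorylation 7 fell (10 adjusted over the list alone), among them Cox5b (−0.73), Atp5j (−0.41) and Uqcrb (−0.33). Of 13 mitochondrially encoded genes 1 fell, mt-Nd1 (−0.29), and 3 adjusted over the list alone. Of 22 redox and metallothionein genes 4 fell (4 lower and 1 higher adjusted over the list alone), the metal-binding Mt1 (−0.94) and Mt2 (−0.83), and Gstm1 and Gsta4. The lists passed camera (adjusted p = 2.54e-18, 2.39e-09, 0.0487 and 0.00284), with adjusted p = 0.238, 0.265, 0.514 and 0.272 with an estimated correlation. Cholesterol synthesis went the other way, with Cyp51 (0.51) and Insig1 (0.44) higher and Stard4 (−0.24) lower of 20 (3 and 1 adjusted over the list alone; camera adjusted p = 0.0184, adjusted p = 0.492 with an estimated correlation).

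Single genes of the barrier changed. Of 17 tight and adherens junction genes, Marveld2, Ctnnb1, or beta-catenin (−0.47, SE 0.07), and Cgnl1 (−0.25) fell and Pard3 (0.21) rose (1 higher and 4 lower adjusted over the list alone). Of 26 transporters of the blood-brain barrier 3 fell and none rose, also adjusted over the list alone, namely Slco2b1 (−0.53), the iron exporter Slc40a1 (−0.37) and the zinc transporter Slc39a10 (−0.28). Of 21 Wnt and barrier transcription factors Foxq1 (−0.40), Tcf7 (−0.44) and Fzd6 (−0.22) fell and the Wnt coreceptor Lrp6 (0.33) rose (3 higher and 6 lower adjusted over the list alone). These 3 lists were lower by camera (adjusted p = 0.00492, 0.00284 and 0.0145), with adjusted p = 0.175, 0.204 and 0.408 with an estimated correlation. They missed the threshold within the larger annotation.

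The 9 remaining lists did not pass as sets in endothelial cells. Cell cycle arrest had 2 of 18 measured genes higher, Gadd45b (1.19, SE 0.22) and Rb1 (0.20, SE 0.06), and 2 lower, the p15 gene Cdkn2b (−0.80, SE 0.13) and Gadd45a (−0.96, SE 0.19), with the same numbers adjusted over the list alone (camera adjusted p = 0.541). Proliferation and lamin B1 had Hmgb1 (−0.43) and Stmn1 (−0.57) lower of 14, and 3 lower adjusted over the list alone (0.504). Caveolae and transcytosis had the adaptor genes Ap2a1 (−0.29) and Ap2m1 (−0.24) lower of 15, as it had adjusted over the list alone (0.229). Angiogenesis and Notch had Pdgfb (0.23) higher of 21 and none adjusted over the list alone (0.773). Vasoregulation had Ace, the angiotensin-converting enzyme (0.92), and Gja5 (1.76) higher and Kcnj2 (−0.58) lower of 17, with 2 and 2 adjusted over the list alone (0.826). Basement membrane had Lama4 (0.47) and Bgn (0.68) higher and Sparc (−0.53) and Itga6 (−0.34) lower of 21, with 3 and 3 adjusted over the list alone (0.255). The TGF-beta and BMP list had the inhibitors Smad6 (0.47) and Smad7 (0.40) higher and Cdh2 (−0.63) lower of 21, the same numbers as adjusted over the list alone (0.822). Of 13 myelin genes Aspa (0.82) rose and none adjusted over the list alone (0.650), and none of 4 haemoglobin genes passed (0.703), with Hbb-bs at 4.62 to 2778 CPM among young libraries alone. The medians of the angiogenesis and Notch (0.05), basement membrane (0.02) and TGF-beta and BMP (−0.07) lists had the other sign within the first batch date, as did cell cycle arrest (0.08) and myelin (−0.49) within the larger annotation. The direction given by camera was down for proliferation and lamin B1 and for vasoregulation, whose medians and means were above 0, and the medians of the angiogenesis and Notch and basement membrane lists lay below 0 and their means above.

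Aged endothelial cells differed from young ones in more genes. Amy1, an amylase (log2 fold change 1.65, SE 0.16), Hdac9 (0.97, SE 0.10) and Kansl1l (0.71, SE 0.08) rose. Sh3pxd2a, a scaffold of podosomes (−1.29, SE 0.09), Marveld2 (−1.30, SE 0.13) and the heat shock cochaperone Bag3 (−1.08, SE 0.11) fell, and all 6 lay beyond the young range in 4 of 4 aged libraries. In all 3328 of 13692 genes passed (edgeR), 1442 higher and 1886 lower. These libraries held immediate early and heat shock genes at 0.209% to 0.276% of endothelial UMIs, below the 0.463% to 0.594% of young ones, and 94.4% to 95.5% of their UMIs fell on genes that both annotations list, against 96.6% to 99.5% in the other 16. Age and these differences lie on the same 4 libraries.

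**Figure D4:**
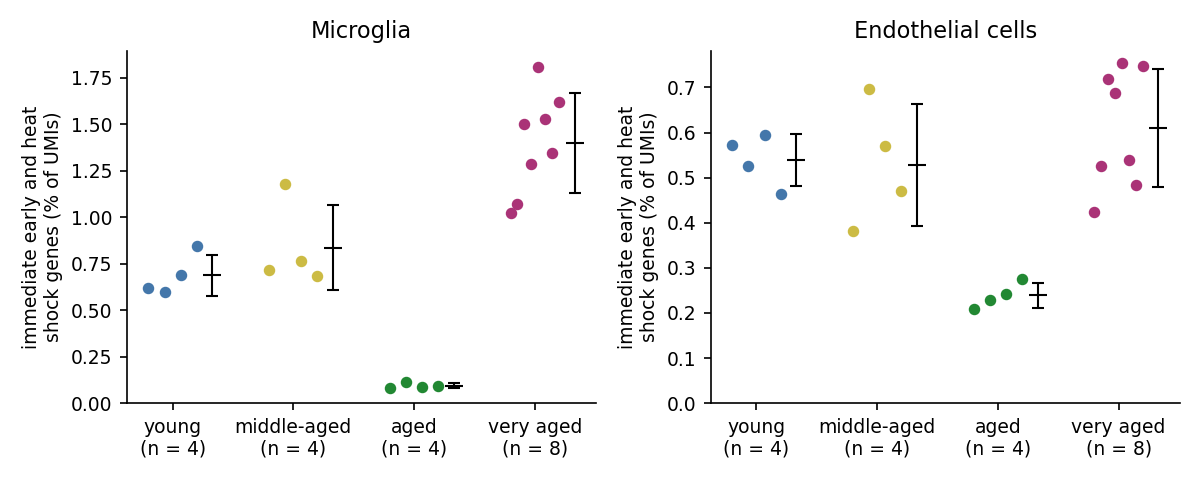
Share of UMIs in immediate early and heat shock genes, in microglia and endothelial cells, in percent by age group. Points are libraries and bars show the mean and SD, with all 4 aged libraries below the other 16 in both classes.

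Middle-aged endothelial cells differed from young ones first in sex-linked genes. Xist stood at 0.194 CPM in young endothelial cells and was higher in 4 of 4 middle-aged libraries (adjusted p = 1.3e-10), as were its antisense Tsix (log2 fold change 9.60, SE 0.72) and X-linked Pcdh11x (3.80, SE 0.25). The Y-linked genes Uty (124 CPM in young), Ddx3y (103) and Eif2s3y (64.4) were lower in 4 of 4, with Ddx3y at a log2 fold change of −4.78 (SE 0.14). In all 651 of 13692 genes passed (edgeR), 394 higher and 257 lower. This count was unstable: 75 with the batch date as a term, 69 within the first batch date, 76 within the smaller annotation, 67 with replicate numbers as a block, 226 without the annotation term, 369 without the aged libraries and 1173 by DESeq2. It was 403 without young 3, 349 without young 4, and 197, 383 and 217 without middle-aged 2, 3 and 4. Age, sex as read from these genes and group label fall on the same libraries.

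Over the order of the 4 age groups, Npas2 (0.42 per group on the log2 scale, SE 0.05), Rasgrf2 (0.27, SE 0.04) and Eml5 (0.25, SE 0.03) rose, and Pomc (−0.49, SE 0.07), Tprgl (−0.21, SE 0.03) and Ubb (−0.28, SE 0.04) fell. Each was beyond all young libraries in 8 of 8 very aged ones. In all 821 of 13692 genes passed (edgeR), 500 higher and 321 lower. The count was 1399 with the batch date as a term and 542 without young 4. Cdkn1a did not pass (−0.06 per group, SE 0.12, adjusted p = 0.874).

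Microglia had the most genes called. Genes of disease-associated microglia, a state of lipid handling and phagocytosis, rose in 17 of 26 measured members and fell in 1 (17 and 2 adjusted over the list alone). Apoe, which carries lipids, went from 184 to 1738 CPM (log2 fold change 3.12, SE 0.40), and Axl (2.85, SE 0.24), Itgax (2.06, SE 0.28) and Ank (0.74, SE 0.10) rose. Homeostatic genes fell in 11 of 15 members and rose in none (13 lower adjusted over the list alone), with Gpr34 (−0.76, SE 0.09), Siglech (−0.59, SE 0.08), the ADP receptor P2ry12 (−0.63, SE 0.09) and Fcrls (−0.53, SE 0.09). All 8 lay beyond every young library in 8 of 8 very aged ones. The interferon response list had 22 of 33 higher (24 adjusted over the list alone), with Isg15 (2.49), Ifi27l2a (2.46), Lgals3bp (1.44) and Usp18 (1.26). MHC class I had 7 of 15 higher and 1 lower (8 and 1 adjusted over the list alone), with H2-Q7 (3.18) and H2-K1 (1.17), and MHC class II 5 of 7 higher and 1 lower, also adjusted over the list alone, with Cd74 (2.18), H2-Aa (2.30) and Ciita (1.43) higher and H2-DMb1 (−0.39) lower. Cdkn1a rose in 8 of 8 libraries (2.47, SE 0.17, adjusted p = 5.32e-09), while Cdkn2a did not pass (0.01, SE 0.28, adjusted p = 0.986). Immediate early and heat shock genes moved with these, with 18 of 24 higher (also adjusted over the list alone; camera adjusted p = 2.11e-08, adjusted p = 0.210 with an estimated correlation) and a share of 1.02% to 1.81% of microglial UMIs in very aged libraries against 0.599% to 0.843% in young ones.

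The single genes with the smallest adjusted p in microglia were Pcbp3 (log2 fold change 2.34, SE 0.11), Ildr2 (1.25, SE 0.06), Dlg5 (2.30, SE 0.12), Adam22 (1.63) and Kcnj12 (1.85) among the risen, and the lysosomal sulfatase gene Arsb (−1.88, SE 0.06), Il7r (−0.92), Gdi2 (−0.51), Sqor (−0.62) and Lypla1 (−0.82) among the fallen. In all 6562 of 15104 genes passed (edgeR), 3304 higher and 3258 lower, and 3699 within the larger annotation and 3728 without the clusters led by markers of another class. By camera, the interferon (adjusted p = 1.49e-09), MHC class I (0.000185) and II (0.0181), disease-associated (6.1e-06) and homeostatic (4.57e-05) lists passed. With an estimated correlation no list did in microglia, with adjusted p = 0.210, 0.210, 0.279, 0.314 and 0.279 for these 5.

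The complement gene C4b rose in oligodendrocytes and astrocytes. In very aged oligodendrocytes the ageing and stress list had 3 of 9 members higher (6 adjusted over the list alone), C4b (log2 fold change 3.32, SE 0.49), Serpina3n, a protease inhibitor (3.86, SE 0.85), and H2-D1 (1.58, SE 0.33), each higher in 8 of 8 libraries, and it passed camera both ways (adjusted p = 4.39e-10, and 0.00433 with an estimated correlation). MHC class I had 4 of 12 higher (5 adjusted over the list alone), with Nlrc5 (3.49), H2-K1 (0.76) and H2-Q7 (3.53), camera adjusted p = 7.49e-08 and adjusted p = 0.0896 with an estimated correlation. Of 13 myelin genes Opalin fell (−0.49, SE 0.11), with 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0764). Eya4 (1.26), Cacna2d3 (1.36), Cacna1a (1.11), the insulin-degrading Ide (0.94) and Grm8 (1.87) rose, and Psd3 (−0.72), Gamt, which makes creatine (−0.83), Tmem141 (−1.26), Hspe1 (−0.70) and Hebp1 (−0.91) fell. In all 440 of 11700 genes passed (edgeR), 215 higher and 225 lower, 182 within the larger annotation, 218 without young 2, 293 without young 4 and 109 with replicate numbers as a block.

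In very aged astrocytes the glutamate receptor gene Grm3 (log2 fold change 0.84, SE 0.10), Fgf13 (0.87), Gnao1 (0.77), Me3 (1.17) and Chrdl1 (1.11) rose, and Csmd2 (−1.60, SE 0.20), Coq10b (−1.19), Fnbp1l (−1.02), Galnt10 (−1.08) and Rtl4 (−2.21) fell. C4b was the 1 of 8 reactive astrocyte genes that rose (1.39, SE 0.28, higher in 8 of 8 libraries; 1 adjusted over the list alone; camera adjusted p = 0.0063, adjusted p = 0.202 with an estimated correlation), and Lgals3bp the 1 of 14 interferon genes (1.06, SE 0.27; 5 adjusted over the list alone; camera adjusted p = 6.08e-05, and adjusted p = 0.0494 with an estimated correlation). Immediate early and heat shock genes, which respond to tissue handling, had the smallest camera p there, with 5 of 17 higher (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.67e-09, and adjusted p = 0.0494 with an estimated correlation). In all 143 of 9659 genes passed (edgeR), 97 higher and 46 lower. The count was 22 within the first batch date, 36 and 51 within the smaller and larger annotation, 65 with replicate numbers as a block, 54 without young 2, 64 without young 4 and 91 without very aged 8.

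Mural cells of vessels were compared gene by gene, and no list was tested as a set in them. In very aged pericytes Ifi27l2a (log2 fold change 3.96, SE 0.55), Isg15 (2.55), Xaf1 (0.75), H2-Q7 (2.08), B2m (0.46) and Cd74 (1.58) rose. So did Syne1 (0.70), Galnt17 (0.73), Ppp2r2b (0.85), Pgm5 (1.21) and Sp100 (1.27), while the imprinted noncoding RNAs Meg3 (−0.77) and Rian (−0.94), Unc13c (−0.56), Sfrp2 (−1.42) and Tnxb (−0.71) fell. Of 10895 genes 321 passed (edgeR), 220 higher and 101 lower, with 150 within the larger annotation, 180 without young 1 and 211 without young 2. In smooth muscle cells H2-K1 (0.65, SE 0.10), B2m (0.53), H2-D1 (0.51), Ifi27 (0.48), Lgals3bp (1.46), Isg15 (0.85) and Xaf1 (0.74) rose, with the sodium and calcium exchanger gene Slc24a3 (1.84, SE 0.12), Cacna2d3 (1.63), Cp (1.11), Vav3 (0.97) and the inflammatory caspase Casp4 (1.92). The Notch target Heyl (−0.87), Nrip2 (−0.95), Olfr558 (−1.74), Cabp1 (−0.77) and Errfi1 (−0.68) fell. Of 10499 genes 523 passed (edgeR), 316 higher and 207 lower, with 256 within the first batch date, 275 within the smaller annotation, 278 without young 4 and 129 with replicate numbers as a block.

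The T or NK class of very aged brains was also compared gene by gene, with no list tested as a set. It pools T and NK cells, so that their mixture cannot be told from changes within cells. The young libraries used held 43, 29 and 22 of its cells. Fcer1g (log2 fold change −3.09, SE 0.22), the killer receptors Klre1 (−3.08), Klrc2 (−2.81) and Klra9 (−5.09) and Aoah (−4.13) fell. Themis, a T cell signalling gene (1.11, SE 0.18), Cdk8 (1.49), Immp2l (1.43), Adam19 (1.38), Nr4a3 (2.56) and Ifi27l2a (1.59) rose, and all of these were beyond the young range in 8 of 8 libraries. Of 4779 genes 158 passed (edgeR; young n = 3, very aged n = 8), 58 higher and 100 lower. The count was 13 within the first batch date and 5 with replicate numbers as a block, and 90 without young 3 and 74 without young 4.

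In border macrophages 36 of 6823 genes passed (edgeR), 21 higher and 15 lower. Cdkn1a (log2 fold change 1.31, SE 0.25), Slfn5 (1.01), Cd209d (2.56), Sbno2 (1.04), Isg15 (1.75), Parp14 (0.75) and Oasl2 (0.93) rose, and Arsb (−1.88, SE 0.20), Rpl10 (−1.27), Ubb (−0.91), Il1rl1 (−1.86) and Hsph1 (−0.90) fell, each in 8 of 8 libraries, and Grik1, which in endothelial cells was high in very aged 5 to 8 alone, was at 0 CPM in young and 32.9 ± 37.7 in very aged libraries (SD, n = 8). In fibroblasts 31 of 4967 genes passed (young n = 3, very aged n = 5), 9 higher and 22 lower, with Dpyd (1.88), Csmd1 (1.86), Sp100 (1.81), Akap7 (1.21) and Slc2a13 (0.99) higher and Rpl10 (−1.50), Ubb (−1.14), Rpl36 (−1.09), Myl12a (−1.13) and Kctd12 (−1.25) lower. With the batch date as a term, with replicate numbers as a block, within the first batch date and within the smaller annotation the counts were 9, 11, 6 and 4 in border macrophages and 0, 0, 3 and 1 in fibroblasts, where all 10 named genes lost their call in each. Without young 4 the counts were 6 and 2. Border macrophages gave 15 without young 2, 18 without young 3 and 21 without very aged 7, and fibroblasts 48 without young 3, 20 without very aged 3 and 18 without very aged 6. No gene passed in choroid plexus epithelium (edgeR 0, with 247 at an unadjusted p under 0.05; DESeq2 2), in neuroblasts or neural progenitors (edgeR 0, with 345; DESeq2 8) or in neutrophils (edgeR 0, with 109; DESeq2 1). Without young 3, choroid plexus epithelium gave 1 and neuroblasts or neural progenitors 3, and neutrophils gave 1 without very aged 5 and 19 without very aged 6.

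Whether ageing acts on endothelial cells as on other cells was tested by comparing the very aged effect between classes of the same libraries. Against microglia the endothelial change was lower for Cdkn1a (difference −2.29 on the log2 scale, SE 0.29, adjusted p = 4.16e-05), Dlg5 (−2.27), Afdn (−1.18) and Pim3 (−2.15), and higher for Naip2 (1.28) and Arsb (1.27), which fell less in endothelial cells. The difference for Cdkn2a did not pass (−0.27, SE 0.65, adjusted p = 0.830). Against astrocytes Acsl6, an acyl-CoA synthetase (1.43), and Npas2 (1.33) were higher, and Slc22a23 (−1.71), Dach1 (−1.25) and Fgf13 (−1.45) lower. Against oligodendrocytes Prkcz (1.42) and Ctps (1.58) were higher, and Clic5 (−1.85), Tgfbr3 (−1.43) and Synm (−0.89) lower. By edgeR 3131 of 16204 genes differed against microglia, 180 of 14661 against astrocytes and 339 of 14521 against oligodendrocytes. These counts were 1458, 8 and 47 within the first batch date, and the last pair was 71 and 168 without young 4.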

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

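The tests of explanations in this part were chosen after the results were seen, while the comparisons they start from were planned.

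In very aged endothelial cells, 7 genes of the disease-associated microglia list and 5 of the leukocyte adhesion list rose together, and microglia were the most abundant class around them (52.4% of kept cells). RNA from microglia, released into the droplets or carried by cells captured together, is a candidate source for the first list: the level expected from the microglial RNA share of each library was a median 0.631 of the level observed (SD 0.332 over the 7 genes), from 1.08 for Ccl4 and 0.953 for Ccl3 to 0.0875 for Csf1. The same test argued against that source for the adhesion list, with a median of 0.00205 (SD 0.0849 over the 5 genes) and 0.193 for Icam1 as the highest. The estimate rests on 17 microglial marker genes, whose RNA share was not shown to differ between very aged and young (exact permutation p = 0.497). Its subtraction in each library (with negative values set to 0) left log2 differences of 0.48 for Lgals3 to 1.68 for Ccl4. Setting values to 0 can leave a positive remainder, so that these differences cannot decide whether microglial RNA gives the whole rise. An effect of age on the vessel wall may stand behind the adhesion genes and remains open. Several of these genes are also markers of venous cells, whose share was not tested as a source. Nor was RNA from neutrophils tested for Lcn2, which was also among the leading genes of a neutrophil cluster. For the microglial list a mixture of microglial RNA and an effect of age also remains open. So does microglial RNA alone for Ccl3 and Ccl4.

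The 4 middle-aged libraries, labelled male, held Xist and few Y-linked transcripts. A mix with cells of males as 10% or more was argued against, since the highest level of Eif2s3y, Uty and Kdm5d together was 0.0387% of the mean of the other 16 libraries, and Ddx3y stood at 1.66 to 4.05 CPM, against 90.9 to 128. A smaller mix was not excluded. A wrong sex in the label of a sample may apply to all 4: 4 of 4 held more than 10 times the Xist of any other library and less than 10% of its Eif2s3y, Uty and Kdm5d together. Because all 4 are in 1 group, age and sex cannot be told apart in middle-aged brains, and no biological explanation other than sex was tested.

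The 4 aged libraries stood apart in their cell mixture and their genes, with 3328 genes called in endothelial cells, and in 4 of 4 the share of immediate early and heat shock genes in microglia lay below all other libraries. Another way of handling or preparing the tissue could lower that share, and a difference between library batches could lower the share of UMIs on genes of both annotations, which was also below all others in 4 of 4. Neither can be told apart from age, since all aged libraries and no others show both, and the labels give these libraries the batch date of the young ones. An effect of age itself also remains open, though the very aged libraries, which are older, held 1.02% to 1.81% of immediate early and heat shock genes in microglia, above all young ones (0.599% to 0.843%).

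Some libraries lay far from the others of their group in a cell class. Astrocytes made up 5.90% of kept cells in young 4 and 2.80% to 3.04% in the other young libraries. Oligodendrocytes made up 7.96% in young 4 and 1.71% to 2.77% in the others. Smooth muscle cells made up 8.45% in young 4 and 3.205% to 3.82% in the others. Choroid plexus epithelium made up 0.165% in aged 2 and 0 to 0.0121% in the other aged libraries. In all 52 sets of libraries were examined. Chance gives about 1 in 20 such sets, but the shares of 1 library sum to 100%, so that the 3 of young 4 are not independent.

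The very aged effect differed between classes by a test of the difference itself. Against microglia 3131 genes differed, against astrocytes 180 and against oligodendrocytes 339. The real split of the libraries gave the highest of 40 counts for each (value 1 each), and the highest other split gave 14, 24 and 87. This argues against chance, though 40 splits do not exclude it, and a top rank does not tell age from batch date or tissue handling.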

How the results depend on the processing

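Among the alternatives in this part, those that used the automatic doublet threshold, left out clusters led by genes of another class, left out the middle-aged or aged libraries or young 2 with very aged 6, or kept the libraries of 1 annotation in gene tests, class differences and lists were chosen after the data were seen.

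The call of 3328 genes in aged endothelial cells stayed within 1.5 times that count under all 13 alternatives (2390 to 3716) and without each library in turn. The count for very aged endothelial cells did so under 13 of 17 alternatives (762 to 1693), the trend under 14 of 15 (624 to 1399), microglia under 10 of 12 (3699 to 6958) and pericytes under 9 of 12 (150 to 578), while the middle-aged count did under 6 of 13 (67 to 1173). Of the values of genes named in very aged endothelial cells, taken over alternatives and left out libraries, 2241 kept direction and call, 518 kept direction and lost the call and 1, Cdkn1a, reversed. In microglia these were 755, 2 and 11, and the 11 were Cdkn2a, whose fold change lay near 0 at first. No named gene reversed in T or NK cells (236 kept direction and call, 40 lost the call), astrocytes (226 and 50), border macrophages (206 and 83), fibroblasts (152 and 72), oligodendrocytes (344 and 32), pericytes (342 and 59) or smooth muscle cells (358 and 33). Those of aged endothelial cells kept direction and call in 143 and reversed in 4, of middle-aged in 144 with 3 that gained a call (Cdkn1a), and of the trend in 242 with 3 reversed, where all that reversed were Cdkn1a. Shares of single classes kept both in 561, lost the call in 85, gained it in 2 and reversed in 28. List medians kept both in 201, lost the call in 41, gained it in 6 and reversed in 22. For the values that follow the cause was not tested. By construction, the settings of 1 date or annotation, the replicate block and those without named libraries hold fewer libraries, and the setting with no low-count filter tests more genes. With 4 pairs in the block, or 2 against 4 libraries in the larger annotation, no share can pass, so that the 0 classes called there say nothing on stability.

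Under the stricter cell filter, the numbers of classes called were 2 in very aged and 0 in aged. Log2 differences of shares were −0.042 for endothelial cells and −0.060 for microglia in very aged, and 0.016 for oligodendrocytes in middle-aged. For smooth muscle cells they were 1.01 in very aged, 0.91 in aged and 1.35 in middle-aged, with a rho of 0.315 over the trend. The share of venous cells in very aged differed by 0.0116 percentage points. Endothelial cells with a Cdkn2a UMI differed from young by −0.00782 points in aged, with a rho of −0.00797 over the trend. Without clusters led by another class, the shares differed on the log2 scale (rho for the trend) by −0.22 for microglia in very aged, 0.029 for smooth muscle cells in middle-aged and −0.0723 for microglia over the trend. In microglia (very aged) 3728 genes were called and the log2 fold change of Cdkn2a was −0.22. Within the first batch date, the classes called numbered 0 in very aged and 0 over the trend. The endothelial share in very aged differed by −0.45 (log2), and arterial cells had a rho of 0.0485 over the trend. Endothelial cells with a UMI differed by 0.0125 (Cdkn2a) and −0.122 (Cdkn1a) percentage points in very aged. The rho over the trend was −0.194 for Cdkn1a. Genes called numbered 13 for T or NK cells, 22 for astrocytes, 6 for border macrophages, 69 for endothelial cells (middle-aged), 3 for fibroblasts, 5 for neutrophils and 256 for smooth muscle cells. Log2 fold changes were −0.37 for Cdkn2a in microglia (very aged). Genes that differed between endothelial cells and another class numbered 8 against astrocytes, 1458 against microglia and 47 against oligodendrocytes. The list medians in endothelial cells were 0.051 for angiogenesis and Notch, 0.015 for basement membrane, −0.066 for TGF-beta and BMP and 0.34 for homeostatic microglia. Within the larger annotation, the numbers of classes called were 0 in very aged and 0 over the trend. Log2 differences of shares in very aged were −0.12 for microglia and −0.11 for oligodendrocytes. The rho over the trend was 0.207 for endothelial cells and −0.207 for microglia and for oligodendrocytes. Venous cells differed by 2.89 percentage points in very aged, with a rho of 0.414 over the trend. Endothelial cells with a Cdkn2a UMI differed by 0.0176 points in very aged. The counts of genes called were 51 for astrocytes, 173 for choroid plexus epithelium, 762 for endothelial cells (very aged), 3699 for microglia, 182 for oligodendrocytes and 150 for pericytes. The numbers of genes with a class difference were 1056 against microglia. Medians of lists (log2) were 0.079 for cell cycle arrest and −0.49 for myelin. Without young 2 and very aged 6, the classes called numbered 0 in very aged. In very aged the endothelial share differed by −0.25 on the log2 scale, and endothelial cells with a Cdkn2a UMI by 0.0462 percentage points. The numbers of genes called were 28 for astrocytes, 6 for border macrophages, 825 for endothelial cells (very aged), 18 for fibroblasts, 7 for neutrophils, 157 for oligodendrocytes, 180 for pericytes and 315 for smooth muscle cells. Genes that differed between endothelial cells and another class numbered 65 against astrocytes and 219 against oligodendrocytes. List medians came to 0.035 for cell cycle arrest and 0.84 for haemoglobin.

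With replicate numbers as a block, 0 classes were called in very aged and 0 in aged. The endothelial share in very aged differed by −0.45 (log2). Genes called numbered 5 for T or NK cells, 65 for astrocytes, 11 for border macrophages, 1 for choroid plexus epithelium, 853 for endothelial cells (very aged), 67 for endothelial cells (middle-aged), 0 for fibroblasts, 2 for neuroblasts or neural progenitors, 7 for neutrophils, 109 for oligodendrocytes and 129 for smooth muscle cells. Log2 fold changes came to −0.20 for Cdkn1a in endothelial cells (very aged) and −0.24 for Cdkn2a in microglia (very aged). The list medians in endothelial cells were 0.030 for angiogenesis and Notch, 0.048 for basement membrane, −0.035 for TGF-beta and BMP, −0.21 for immediate early and heat shock and 0.50 for homeostatic microglia. At Leiden resolution 0.6, the classes called numbered 0 in aged. Arterial, capillary and venous shares in very aged differed by 1.99, −5.90 and 2.73 percentage points. Their rho over the trend was 0.226, −0.440 and 0.179. Among cells outside the most abundant class, the numbers of classes called were 0 in aged. Without the middle-aged libraries, the trend had a rho of 0.0320 for smooth muscle cells and 0.0959 for venous cells. The log2 fold change of Cdkn1a in endothelial cells (trend) was 0.076. Without the middle-aged and aged libraries, 2 classes were called over the trend and 1 gene in neuroblasts or neural progenitors. The log2 fold change of Cdkn1a in endothelial cells (trend) came to 0.081.

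Thinned to 500 UMIs, endothelial cells with a Cdkn2a UMI differed from young by 0.00134 percentage points in very aged and 0.0215 in middle-aged. Their rho over the trend was −0.0528. Without thinning, those with a Cdkn1a UMI differed by −8.77 points in very aged, 0.327 in aged and −0.728 in middle-aged. The rho over the trend was then −0.353 for Cdkn2a and −0.472 for Cdkn1a. With no low-count filter, the numbers of genes called were 277 for T or NK cells, 336 for astrocytes, 99 for border macrophages, 103 for choroid plexus epithelium, 133 for fibroblasts, 114 for neuroblasts or neural progenitors, 4 for neutrophils, 765 for oligodendrocytes, 578 for pericytes and 841 for smooth muscle cells. Log2 fold changes were 0.0094 for Cdkn1a in endothelial cells (aged) and −0.017 for Cdkn2a in microglia (very aged). With a batch date term, genes called numbered 11 for T or NK cells, 38 for astrocytes, 9 for border macrophages, 75 for endothelial cells (middle-aged), 1399 for endothelial cells (trend), 0 for fibroblasts, 1 for neutrophils, 274 for oligodendrocytes and 250 for smooth muscle cells. Log2 fold changes came to −0.37 for Cdkn2a in microglia (very aged). Medians of lists (log2) were 0.055 for angiogenesis and Notch, 0.018 for basement membrane, −0.068 for TGF-beta and BMP and 0.35 for homeostatic microglia. Within the smaller annotation, the counts of genes called were 13 for T or NK cells, 36 for astrocytes, 4 for border macrophages, 890 for endothelial cells (very aged), 76 for endothelial cells (middle-aged), 1 for fibroblasts, 3 for neuroblasts or neural progenitors, 5 for neutrophils and 275 for smooth muscle cells. Log2 fold changes were −0.38 for Cdkn2a in microglia (very aged). The numbers of genes with a class difference were 14 against astrocytes, 1377 against microglia and 57 against oligodendrocytes. List medians came to 0.080 for angiogenesis and Notch, 0.041 for basement membrane, −0.041 for TGF-beta and BMP and 0.38 for homeostatic microglia.

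By DESeq2, the numbers of genes called were 2 for choroid plexus epithelium, 1173 for endothelial cells (middle-aged), 8 for neuroblasts or neural progenitors and 1 for neutrophils. With no annotation term, genes called numbered 226 for endothelial cells (middle-aged) and 20 for fibroblasts. The list medians in endothelial cells were −0.036 for homeostatic microglia. Without the aged libraries, 369 genes were called in endothelial cells (middle-aged). With an estimated correlation, the number of lists called fell to 1.

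With each library left out in turn, the numbers of classes called were 0 to 1 in very aged and 0 to 7 in aged. The very aged call of T or NK cells ended without any of young 1 to 4, where 1 class alone cannot pass (log2 difference 2.52 to 2.96). The aged calls ended without any 1 library except aged 1. Log2 differences of shares were −0.13 to 0.29 for endothelial cells and −0.054 to 0.16 for microglia in very aged. In middle-aged they were −0.62 to 0.23 for oligodendrocytes and −0.43 to 0.31 for smooth muscle cells. Endothelial cells reversed without young 1 (−0.016), young 2 (−0.13) or very aged 6 (−0.048), microglia without young 4, middle-aged oligodendrocytes without young 4 or middle-aged 2 (0.011), and middle-aged smooth muscle cells without young 4 or middle-aged 1 (0.28) or 2 (0.25). The shares of endothelial types in very aged differed by percentage points of −6.48 to −3.76 for arterial and 3.34 to 10.3 for capillary. The far ends, −6.48 and 10.3, came without young 3. For endothelial types the rho of the trend was −0.0443 to 0.230 for capillary and −0.191 to 0.0230 for venous. Capillary cells reversed without young 1 or 2 (−0.0443) or 4 (−0.0194), and venous cells without young 1 or 4 (0.0230). Endothelial cells with a Cdkn2a UMI differed from young by −0.0245 to 0.0419 percentage points in very aged, −0.0203 to 0.0460 in aged and −0.0286 to 0.0377 in middle-aged. Cdkn2a turned in very aged without young 2 (0.0419), very aged 2, 3 or 5 (0.00411) or very aged 6 (0.000264), in aged without young 1 or 4 (−0.0203), young 3 (−0.00495) or aged 1 (−0.0103) or 4 (−0.00331), and in middle-aged without young 2 (0.0377) or middle-aged 1 (0.00948). The trend of cells with a UMI had a rho of −0.0577 to 0.185 for Cdkn2a and −0.0608 to 0.135 for Cdkn1a. For Cdkn2a it turned without young 1 or 4 (−0.0577), very aged 1, 4 or 7 (−0.0329) or middle-aged 1 (−0.0121), and for Cdkn1a without young 2 or 4 (−0.0608), very aged 6 (−0.0109) or very aged 8 (−0.0456). The numbers of genes called were 74 to 207 for T or NK cells, 54 to 189 for astrocytes, 6 to 30 for border macrophages, 0 to 1 for choroid plexus epithelium, 774 to 1327 for endothelial cells (very aged), 197 to 951 for endothelial cells (middle-aged), 542 to 832 for endothelial cells (trend), 2 to 48 for fibroblasts, 0 to 3 for neuroblasts or neural progenitors, 0 to 19 for neutrophils, 218 to 428 for oligodendrocytes, 180 to 322 for pericytes and 278 to 527 for smooth muscle cells. Counts moved by over 1.5 times for T or NK cells without young 3 (90) or 4 (74), for astrocytes without young 2 (54), young 4 (64) or very aged 8 (91), and for border macrophages without young 2 (15), 3 (18) or 4 (6) or very aged 7 (21). They did so for very aged endothelial cells without young 4 (774), for the trend without young 4 (542), and for middle-aged ones without young 3 (403) or 4 (349) or middle-aged 2 (197), 3 (383) or 4 (217). Fibroblasts moved without young 3 (48) or 4 (2) or very aged 3 (20) or 6 (18), oligodendrocytes without young 2 (218) or 4 (293), pericytes without young 1 (180) or 2 (211), smooth muscle cells without young 4 (278), neutrophils without very aged 5 (1) or 6 (19), and choroid plexus epithelium and neuroblasts or neural progenitors without young 3. Log2 fold changes came to −0.20 to 0.41 for Cdkn1a in endothelial cells (aged), −0.12 to 0.0027 for Cdkn1a in endothelial cells (trend) and −0.18 to 0.18 for Cdkn2a in microglia (very aged). Cdkn1a reversed in aged cells without young 1, aged 2 (0.064) or aged 3 (0.012) and over the trend without middle-aged 3, and Cdkn2a in microglia without young 3 (−0.053), young 4 (−0.13) or very aged 3 (−0.072), 5 (−0.0059) or 7. Genes that differed between endothelial cells and another class numbered 71 to 213 against astrocytes and 168 to 370 against oligodendrocytes. The counts against astrocytes were 83 without young 2, 71 without young 4 and 114 without very aged 8, and the lowest against oligodendrocytes came without young 4.

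Some alternatives gave no value. The larger annotation holds no middle-aged or aged libraries, so that neither was compared with young there, and the share tests were not run within the smaller annotation. Replicate numbers as a block left out very aged 5 to 8 from the share tests, since no younger library has these numbers, and in the gene tests each of the 4 held a term of its own and so did not count. Depth limits the senescence markers: with 7 of 12316 very aged and 3 of 6162 young endothelial cells positive for Cdkn2a, the sign of its difference turned with single libraries. In simulated data 46% of genes changed by 0.5 on the log2 scale were called in endothelial cells and 9% in astrocytes. Smaller changes can be missed.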

Other observations

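The tests of hypotheses and the regroupings of libraries in this part were chosen after the results were seen.

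Microglia and glia held further changes. In very aged microglia the cholesterol synthesis list had 11 of 20 genes higher and none lower (12 higher adjusted over the list alone; camera adjusted p = 0.000185, or 0.210 with an estimated correlation), and the senescence secretory list 34 of 63 higher and 6 lower (34 and 6 adjusted over the list alone; camera adjusted p = 4.76e-06, or 0.184 with an estimated correlation). Leukocyte adhesion had 5 of 8 higher, also adjusted over the list alone (camera adjusted p = 0.00115, or 0.114 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 14 of 53 lower and none higher (10 lower adjusted over the list alone; camera adjusted p = 0.00293, or 0.549 with an estimated correlation), while 5 of 13 mitochondrially encoded genes were higher (5 adjusted over the list alone; camera adjusted p = 0.0299, or 0.482 with an estimated correlation). Ribosomal protein genes had 2 of 77 higher and 2 lower (none adjusted over the list alone), with camera adjusted p = 0.647. In very aged astrocytes cholesterol synthesis had 2 of 17 lower (7 adjusted over the list alone; camera adjusted p = 3.35e-08, or 0.101 with an estimated correlation). Mitochondrially encoded genes had 3 of 13 lower there (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 8.51e-06, or 0.101 with an estimated correlation). In very aged oligodendrocytes ribosomal protein genes had 5 of 76 lower (13 adjusted over the list alone; camera adjusted p = 4.27e-11, or 0.265 with an estimated correlation). Immediate early and heat shock genes had 3 of 24 higher and 5 lower there (7 and 8 adjusted over the list alone; camera adjusted p = 0.450).

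Fenestrated endothelial cells, the leaky type found outside the blood-brain barrier, made up 10.4% ± 7.07 of endothelial cells in very aged brains (SD, n = 8) and 6.70% ± 2.51 in young ones (SD, n = 4), with 22.7% as the highest of the very aged libraries. Neutrophils made up 9.35% of kept cells in very aged 6, and unnamed clusters 29.0% in young 2.

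The later batch date, held by very aged 5 to 8 alone, came with genes of its own. In at least 1 of 6 classes 25 genes had a lowest level, with 3 CPM added, over 2 times the highest of the other libraries with as much added. The others were those with over 200000 UMIs in the class, 16 in 4 classes, 13 in oligodendrocytes and 12 in astrocytes. Of these genes 10 did so in 4 or more classes and 4 in all 6 (5830416I19Rik, 8430422H06Rik, Klhl14 and Xlr5a). In endothelial cells Xlr5a stood at 20.4 to 48.1 CPM in these 4 libraries and at 0.862 or less elsewhere.

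Cdkn1a rose in microglia of very aged brains. After thinning, 2.55% to 5.06% of microglia had a Cdkn1a UMI in the very aged libraries and 0.421% to 1.19% in the young ones, higher in 8 of 8 (exact two-sided permutation test, p = 0.00202, the smallest that 4 against 8 libraries can give). At such low counts this share restates the rise in summed counts, and more positive cells cannot be told apart from more RNA per cell. Tissue handling could also raise Cdkn1a. With a slope on the share of immediate early and heat shock genes, fitted within groups (0.73 ± 0.32 SE), 1.69 ± 0.39 (SE) of the log2 difference of 2.43 was left, which leaves handling open. Cells that are senescent were not identified by this test, and Cdkn2a in microglia did not pass.

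Regroupings of the same libraries showed whether chance can be argued against for each count of genes. It can for very aged against young endothelial cells (1369, and at most 100 in the other splits of 100), for aged against young (3328, at most 383 in the other splits of 35), for middle-aged against young (651, at most 5 of 35) and for the trend (821, at most 198 of 100). It can as well for microglia (6562, at most 1894), astrocytes (143, at most 43), oligodendrocytes (440, at most 92), pericytes (321, at most 41), smooth muscle cells (523, at most 120), T or NK cells (158, at most 22), border macrophages (36, at most 4) and fibroblasts (31, at most 14 in 56 splits), where 1 split, the real one, gave as many. For the classes with no gene called the test says nothing, since every split gives at least 0 genes: 100 of 100 for choroid plexus epithelium (0, highest other 154), 35 of 35 for neuroblasts or neural progenitors (0, highest other 2) and 35 of 35 for neutrophils (0, highest other 37). The splits with 154 and 37 genes may point to a structure of those libraries, but what they share was not tested.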
